A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

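RNA of 9 cultures of strain JPY12, with histone H3 on a plasmid, was measured with 1 array per culture: K42A, K42L and K42Q with 2 arrays each and wild type with 3. Per the labels' protocols, cells grew in YPD to log phase, total RNA was taken with hot phenol and a column, and biotin-labelled RNA was made by 1 round of T7 amplification. The deposited values are array signal intensities on a linear scale, per the labels made with GCOS 1.4 and MAS5. The version of MAS5 and the target of the scaling are not given in the sources used here. The mean of each array's signals, trimmed by 2 percent on each side, was 150.1, so the deposited signals had been scaled to a common mean.

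Signals were used as log2 with no further scaling, and 126 of 98352 values at 0 were set to the smallest positive value, 0.1. Of 10928 probe sets, 5498 were named with 1 S. cerevisiae gene, 1747 with another listed gene, 3517 with no gene, and 166 were controls. The 1747 include 1 with several genes. The brightest probe set stood for each gene, which gave 5449 genes. Of 47 genes with more than 1 probe set 37 were tested. Among all 47, probe sets lay over 0.5 log2 apart from 0 in opposite directions for 0 genes in K42A and 3 in K42Q. Of these, YOL166W-A was not tested. Genes under the 25th percentile of mean log2 signal, a signal of 87.0, were left out, and 4087 were tested. Among the probe sets with no single gene 142 lay above that signal, and these entered 1 alternative alone. The 1747 probe sets with another listed gene, taken as those of another yeast species, gave the background of each array. Its 95th percentile was at most 9.6.

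Groups were compared with limma 3.58.1 in R 4.3.3 by 1 linear model with a mean per group over all 9 arrays, which pools the spread, and moderated statistics with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each mutant and the mean of the 3 mutants were set against wild type, and the mutants against each other. Of 41 gene lists, 37 had at least 4 measured members and were tested with camera, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison, and again with an estimated correlation. The lists were written from general knowledge, and the 320 outermost genes came from the order of genes on the chromosomes, 10 at each of 32 ends. The comparisons, tests, filter, lists and rule for naming genes were fixed before the data were examined.

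The rule named, per mutant or mean of the mutants against wild type, the 10 largest increases and the 10 largest decreases among called genes whose arrays did not overlap, and 6 of each between mutants. It also named the smallest 5 p-values where fewer than 5 genes passed, all measured histone genes, ACT1, and the 3 members with the largest change of each list called. With 2 arrays against 3, no overlap arises by chance in 20 percent of unchanged genes. Other genes named in the text, such as those of the strain checks, were chosen after their values were seen.

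The labels name no array batch. It was read from the background probe sets after the data were seen, and the batch as a block, fits within the batch, and scaling to the spike-ins within and across the batches were added then. Where K42L or K42Q is fitted within its batch, wild type is a single array, assumed to vary like the others. With the batch as a block, their fold changes against wild type rest on that same array. Blocked comparisons of K42A with K42L or K42Q also use it. Alternatives chosen before the data were examined were quantile scaling, median centring, cyclic loess, other filters, an added 16 before the logarithm, no intensity trend, robust hyperparameters, the compared groups alone, array weights, other probe set rules, the replicate number as a block, a 2-fold threshold, an estimated correlation and leaving out each array. Shared calls between mutants were set against 100 simulations of unchanged groups with the same controls.

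The model was tested on simulated data with 200 of 4087 genes changed, over 20 runs. It recovered 89.6 percent of changes of 0.5 log2 and 99.5 percent of changes of 1, with 10.4 false calls a run. It made 0.15 calls a run in an unchanged comparison. A list shifted by 0.3 was found in 20 of 20 runs, and 0.55 other lists a run were called with it. The simulated noise was independent between genes and held no batch difference. These runs therefore do not show how calls hold under correlated genes or batches. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Arrays of 2 cultures per mutant limit the precision of each value.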

Results

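Transcript levels were measured in 9 cultures of budding yeast on 1-colour Affymetrix arrays, with 1 array per culture. Each strain carried histone H3 on a plasmid, with lysine 42 kept (wild type, n = 3) or replaced by alanine (K42A, n = 2), leucine (K42L, n = 2) or glutamine (K42Q, n = 2). Unlike lysine, none of the 3 residues carries a charge, and glutamine is the usual stand-in for an acetylated lysine. The series title names the residue as a methylated site that holds back transcription. Cultures grew in rich medium to an A600 of about 0.7. The trimmed mean signal was 150.1 on each array, and the median signal of the 4087 genes tested lay between 240.3 and 260 on the 9 arrays. Probe sets for another yeast species, which measure background, had a 95th percentile of 4.4 to 9.6, far below the signal of 87.0 that a gene's mean had to reach. The number of arrays limits the precision of every value here.

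The H3 gene HHT2 (YNL031C) had a signal of 1354 to 1826 on the 9 arrays. HHT1, the other H3 gene, lay between 0.3 and 13.1 and passed the background of its array on 1 array. A probe set cannot read the substitution on the plasmid, so neither gene checks the labels. HIS3 (YOR202W) had a signal of 1852 to 3171 on 8 arrays and of 326 on K42Q replicate 2. Of genes specific to a cells, STE2 lay between 1175 and 2088 and MFA1 between 399 and 843. Of those specific to alpha cells, MF(ALPHA)1 lay between 4.8 and 16.1 and passed the background on 8 arrays. STE3 was not tested, with 27.3 to 29.6 in wild type, 34.1 and 37.9 in K42L, 56.7 and 61.6 in K42A and 59.1 and 62.7 in K42Q. SAG1 lay between 99.6 and 269.

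Background split the arrays into 2 batches that the labels do not name. K42L, K42Q and wild-type replicate 1 had a median background signal of 1.0 to 1.3 and a mean spike-in signal of 418 to 474. K42A and wild-type replicates 2 and 3 had 2.2 to 2.7 and 211 to 265. Within its batch K42A rests on 2 wild-type arrays, and K42L and K42Q each rest on wild-type replicate 1 alone. The same holds for their fold changes with the batch as a block, so the block and the within-batch fits are not separate checks of these. Purine synthesis genes differed between the wild-type arrays of the batches: ADE17 (YMR120C) was at 1415 on replicate 1 and at 122 and 137 on the other wild-type arrays. So did PHO84 (YML123C), for a phosphate transporter, at 41.6 against 755.5 and 852. The first principal component (58.1% of the variance) set K42A and K42Q apart from K42L and wild type, and the second (23.7%) set the batches apart. Values are relative to the trimmed mean of each array. Spike-ins cannot show steps before they were added, so scaling to them does not give RNA per cell. Scaling to the spike-ins within the batch moved the median log2 change of all genes to 0.16 in K42A, 0.06 in K42L and 0.19 in K42Q. Scaling to them across the batches moved it to 0.46, -0.52 and -0.40.

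**Figure D1:**
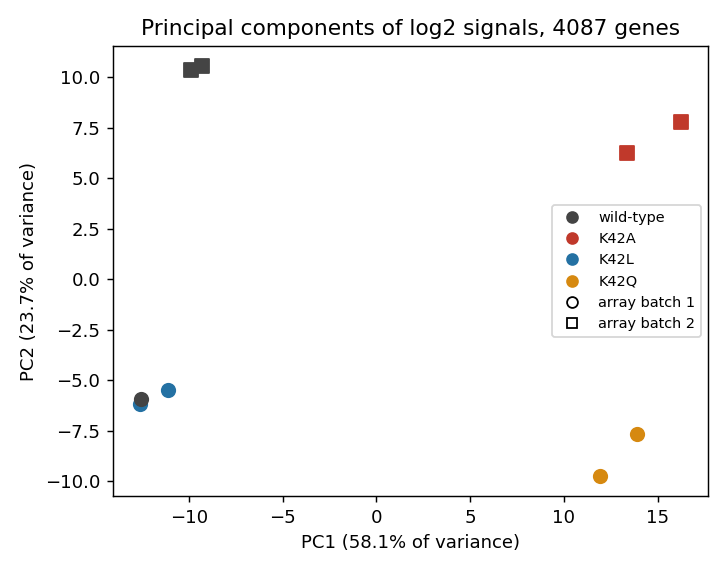
Principal components 1 and 2 of the log2 signals, with each point an array, colour the group and shape the array batch. K42A and K42Q lie on the right and K42L and wild type on the left, along 58.1% of the variance.

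The comparison of K42A with wild type asks what the loss of the lysine does to transcript levels. Stress genes were among those that rose most: DDR2 (YOL052C-A) rose by 2.82 ± 0.20 on the log2 scale (SE, n = 2 against 3), with signals of 616 and 739 against 78.4 to 117 in wild type. TMA10 (YLR327C) rose by 2.76 ± 0.23 and MSC1 (YML128C) by 2.24 ± 0.10, with batch-blocked values of 3.01 and 2.31. Chaperone genes, which heat shock factor drives, rose with them: HSP42 (YDR171W) by 2.05 ± 0.12, HSP78 by 1.67 ± 0.12 and HSP26 by 1.63 ± 0.09. NCA3 (YJL116C) rose by 2.41 ± 0.18, FIG2 (YCR089W) by 2.22 ± 0.15 and PIR3 (YKL163W) by 2.05 ± 0.18. PIR3 is on the cell wall integrity list, which was not called (7 higher, 5 lower of 27, median -0.06, adjusted p of 0.867). Iron uptake genes fell: FIT2 (YOR382W) fell by 0.95 ± 0.13, FET3 (YMR058W) by 0.92 ± 0.10 and ARN1 (YHL040C) by 0.86 ± 0.14, while the low-affinity iron transporter gene FET4 rose by 1.25 ± 0.17.

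Of the 39 measured genes of the general stress response, which the factors Msn2 and Msn4 drive, 31 rose, 0 fell and 8 did not pass. Adjusted over the list alone, 33 rose. The list's median log2 change was 0.89, and 0.99 with the batch as a block or within the batch. Its shift against all other genes had an adjusted p of 2.14e-15 by camera and 0.0386 with an estimated correlation, the only list of this comparison to hold there. It was not called with an estimated correlation and the batch as a block (adjusted p = 0.198), nor within the batch (adjusted p = 0.476). That was the lowest value of any K42A list within the batch. With 2 arrays per group there, the fit could hardly call a list and cannot decide the shift. No list of any comparison was called with an estimated correlation and the block, where the lowest adjusted p was 0.106. All 5 stationary phase genes rose (median 1.54, 1.29 within the batch), led by SNZ1 at 1.87 ± 0.16, and the list had adjusted p = 0.445 with an estimated correlation. In the heat shock list 13 of 24 rose and 1 fell (median 0.57, 0.42 within the batch), with adjusted p = 0.445 with an estimated correlation. These lists share genes, so their shifts are not independent in any comparison. HSP26 and SSA3 are on the general stress, heat shock and stationary phase lists. HSP42, HSP104 and SSA4 are on both the general stress and the heat shock list. The list of PAU, TIR and DAN genes of the cell wall, many of them near chromosome ends, had 12 of 18 higher and 0 lower (median 0.61, 0.42 within the batch). Adjusted over the list alone, 15 rose, and the list had adjusted p = 0.526 with an estimated correlation. The outermost 10 genes of each chromosome end, which silent chromatin covers in part, had 50 higher and 11 lower of 115 measured (median 0.21, 0.22 within the batch), led by MSC1, GTT2 at 1.94 ± 0.19 and PCK1 at 1.82 ± 0.14. In the DNA damage list 10 of 17 rose and 0 fell (median 0.40, 0.20 under quantile, 0.23 under cyclic loess and 0.63 under spike-in scaling within the batch), led by RAD16 at 0.96 ± 0.13. Both of these lists had adjusted p = 0.445 with an estimated correlation.

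Lists of cytosolic ribosomal protein, ribosome biogenesis and RNA polymerase genes were lower in K42A, while the median of mitochondrial ribosomal protein genes was 0.05. Among 128 genes for cytosolic ribosomal proteins, 0 rose, 64 fell and 64 did not pass, and 92 fell adjusted over the list alone. Their median was -0.31, and -0.21 within the batch. It lay between -0.39 and -0.03 over the scalings other than the spike-ins across the batches. The -0.03 came under cyclic loess, which aligns the signal distributions. Among the brightest 818 of all genes tested the median in K42A was -0.25. Whether this list fell by more than other genes of like signal was not tested. RPS22B (YLR367W) fell by 1.06 ± 0.09 and RPL22B (YFL034C-A) by 0.63 ± 0.10. In ribosome biogenesis 2 rose and 37 of 87 fell, also when adjusted over the list alone (median -0.21, -0.29 within the batch), with RRP8 down by 0.61 ± 0.09 and ROK1 by 0.56 ± 0.10. RNA polymerase I and III had 1 higher, RRN6, and 12 lower of 22 (median -0.25), and RNA polymerase II had 0 higher and 6 lower of 12 (median -0.22). RPB5, RPO26 and RPB8 were each called lower, and their calls ended with spike-in scaling within the batch, and their signs turned across the batches (0.11, 0.12 and 0.14). Of 55 Gcn4 targets for amino acid synthesis, 2 rose and 28 fell (median -0.28, -0.22 within the batch), among them LEU9 by 0.78 ± 0.09. The iron list had 4 higher and 12 lower of 22 (median -0.31, with adjusted p = 0.0398 with the batch as a block and 0.0571 within the batch), and the a-specific mating list had 1 higher, ASG7, and 5 lower of 7 (median -0.56), with BAR1 down by 0.72 ± 0.07. SAG1, of the other mating type, rose by 0.83 ± 0.12 (0.71 with the batch as a block). Spike-in scaling within the batch left medians of -0.10 for ribosome biogenesis, -0.07 for RNA polymerase I and III, -0.08 for RNA polymerase II, -0.04 for Gcn4 targets, -0.10 for iron genes and -0.30 for a-specific genes. With an estimated correlation the adjusted p of these lists lay between 0.445 and 0.536. Lipid synthesis (3 higher, 11 lower of 31, median -0.16) changed sign to 0.0043 under quantile, to 0.025 under cyclic loess and to 0.04 under spike-in scaling within the batch, and INO1 and OPI3 rose by 1.48 ± 0.23 and 1.26 ± 0.13 within it. The purine list (0 higher, 5 lower of 18, median -0.29) passed no longer within the batch, where its median was -0.13 (adjusted p = 0.222), and turned to 0.05 with spike-in scaling there. Lipid and purine lists had adjusted p = 0.445 and adjusted p = 0.667 with an estimated correlation.

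Of the histone genes tested, HTA1 fell by 0.37 ± 0.08, HTB1 by 0.25 ± 0.07, HTA2 by 0.23 ± 0.08 and HHF1 by 0.20 ± 0.07 in K42A, and HHT2 (-0.22 ± 0.08) did not pass, with an adjusted p of 0.0516. The sign of HTA2 turned under quantile scaling (0.011), cyclic loess (0.021) and both spike-in scalings (0.0034 and 0.24), and across the batches the spike-ins also turned HTA1 to 0.10, HTB1 to 0.22 and HHF1 to 0.27. Over the list the shift had an adjusted p of 0.0898, and of 0.055 with the batch as a block, with 0 higher and 6 lower of 8. Within the batch the list was called lower (adjusted p of 0.0391), also with 0 higher and 6 lower, but adjusted p = 0.651 with an estimated correlation. Its median was -0.22, -0.21 within the batch and 0.01 under cyclic loess scaling. ACT1, a control gene, was at -0.27 ± 0.12 (adjusted p of 0.0999).

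In all, limma called 925 genes higher and 807 lower in K42A of 4087 tested, and 127 and 2 of them changed by at least 2-fold. With the batch as a block the counts were 1111 and 1129, and within the batch 1067 and 1179. Of the genes called without the block, 919 of the higher and 804 of the lower were also called with it. Median centring gave 734 higher and 1198 lower, spike-in scaling within the batch 1146 and 115, and spike-in scaling across the batches 567 and 0. Without K42A replicate 2 the counts fell to 587 and 334, and without K42A replicate 1 the lower count fell to 488. Of 37 lists tested, 6 were higher and 9 lower, and 14 of them also passed in the same direction with the batch as a block. The block added calls of the lists of G1 and S phase genes (median -0.18, 5 higher and 15 lower of 31) and M and G1 phase genes (-0.24, 2 higher and 13 lower of 24).

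**Figure D2:**
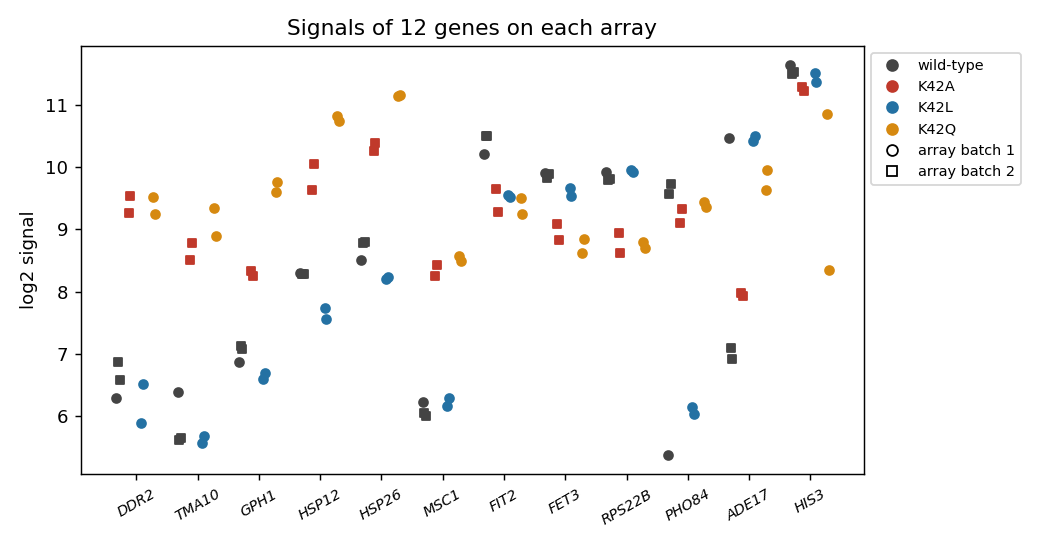
Log2 signals of 12 genes on each array, with colour for the group and shape for the array batch. DDR2, TMA10, GPH1, HSP12, HSP26 and MSC1 lie higher on the K42A and K42Q arrays than on all K42L and wild-type arrays, whereas PHO84 and ADE17 differ between wild-type replicate 1 and the other wild-type arrays.

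The comparison of K42Q with wild type asks the same for glutamine. Stress genes rose here too: TMA10 rose by 3.22 ± 0.23 (SE, n = 2 against 3; 2.72 within the batch), EGO4 (YNR034W-A) by 2.87 ± 0.12, DDR2 by 2.81 ± 0.20 and GPH1 (YPR160W), for glycogen phosphorylase, by 2.65 ± 0.10. HSP12 (YFL014W) rose by 2.48 ± 0.11 and HSP26 (YBR072W) by 2.46 ± 0.09, to signals of 1699 to 1804 and 2260 to 2288. YRO2 (YBR054W) had the largest value, 3.29 ± 0.57, which was 1.79 ± 0.20 with the batch as a block. The copper transporter gene CTR3 rose by 2.87 ± 0.80 and was not called with the batch as a block (0.88 ± 0.41, adjusted p of 0.103), nor without either K42Q array or wild-type replicate 3. Iron uptake genes fell: ARN2 (YHL047C) fell by 1.63 ± 0.11, ENB1 (YOL158C) by 1.51 ± 0.12, SIT1 (YEL065W) by 1.45 ± 0.11 and FET3 by 1.14 ± 0.10. DAN1 (YJR150C), a cell wall gene, fell by 1.70 ± 0.20, and the fall of HIS3 by 1.94 ± 0.53 rests on K42Q replicate 2.

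In the general stress list of K42Q 34 of 39 genes rose, 0 fell and 5 did not pass, and 35 rose adjusted over the list alone. The median was 1.26, and 1.45 within the batch, with an adjusted p of 7.17e-22 by camera and 0.0169 with an estimated correlation, again the only list to hold. It too was not called there with the batch as a block (adjusted p = 0.287) or within the batch, where 1 wild-type array leaves too little to decide. In the heat shock list 16 of 24 rose and 0 fell (median 0.65, 0.58 within the batch), with SSA4 at 2.27 ± 0.15 and SSA3 at 2.07 ± 0.21, and adjusted p = 0.272 with an estimated correlation. All 5 stationary phase genes rose (median 1.27, 1.58 within the batch; adjusted p = 0.439 with an estimated correlation). Genes for mitochondrial ribosomal proteins rose in K42Q: 42 of 65 rose, 0 fell and 23 did not pass, also adjusted over the list alone, led by RSM19 (YNR037C) at 0.83 ± 0.07. Their median was 0.30, and 0.32 within the batch, and the list had adjusted p = 0.361 with an estimated correlation. The iron list had 2 higher and 14 lower of 22 (median -0.42, -0.52 within the batch; adjusted p = 0.439 with an estimated correlation).

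Of 87 ribosome biogenesis genes 2 rose and 31 fell, among them DBP2 (YNL112W) by 1.08 ± 0.07 and TIF6 by 0.63 ± 0.07. Their median of -0.19 became 0.0091 within the batch, where the list was not called (adjusted p = 0.177). Of 128 cytosolic ribosomal protein genes 1 rose and 12 fell, and 0 and 5 adjusted over the list alone. With the batch as a block 1 rose and 86 fell, and within the batch 1 and 37. Their median was -0.09, -0.28 within the batch and 0.012 under cyclic loess scaling, and without wild-type replicate 1 it was -0.0029 (adjusted p = 0.588). RPS22B fell by 1.09 ± 0.09 as it did in K42A. RPL41A was at -0.81 ± 0.71 and not called, and was called higher within the batch (0.96). Gcn4 targets had 3 higher and 17 lower of 55 (median -0.14, -0.37 within the batch), with ILV1 down by 0.92 ± 0.06, GCV1 up by 2.20 ± 0.41, and HIS4 not called (0.97 ± 0.49) but called lower with the batch as a block (-0.37). RNA polymerase I and III (1 higher, 6 lower of 22, median -0.14) and lipid synthesis (2 higher, 11 lower of 31, median -0.11) were not called within the batch (adjusted p = 0.134 and 0.052), and spike-in scaling within the batch turned them to 0.08 and 0.03 and ribosome biogenesis to 0.18. The a-specific list had 0 higher and 5 lower of 7 (median -0.46), and the wider pheromone list 4 higher and 11 lower of 24 (median -0.28; adjusted p = 0.052 within the batch), with GPA1 down by 0.83 ± 0.11. The G2 and M phase list had 1 higher, YRO2, and 8 lower of 22 (median -0.22, -0.30 within the batch), with CLB1 down by 0.74 ± 0.18. The DNA damage list had 8 higher of 17 (median 0.23, 0.09 under quantile and 0.40 under spike-in scaling within the batch), led by HUG1 at 0.91 ± 0.13, and the oxidative stress and efflux list 11 higher and 2 lower of 25 (median 0.28; adjusted p = 0.134 within the batch), led by TSA2 at 1.97 ± 0.23. The outermost genes had 42 higher and 19 lower of 115 (median 0.11, 0.18 within the batch). With an estimated correlation the adjusted p of these lists lay between 0.361 and 0.761.

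No histone gene was called in K42Q: HTA1 was nearest (-0.21 ± 0.08, adjusted p of 0.0595) and was called with the batch as a block (-0.26, adjusted p of 0.0299). In all, 873 genes rose and 745 fell in K42Q, 110 and 17 of them by at least 2-fold. With the batch as a block the counts were 923 and 843, of which 684 and 550 were called both ways, and within the batch they were 979 and 780. Quantile scaling gave 705 higher and 947 lower, spike-in scaling within the batch 1636 and 357, and across the batches 49 and 79. Without K42Q replicate 1 the counts were 477 and 377, without replicate 2 577 and 431, and without wild-type replicate 1 the lower count was 1137. Of 37 lists 7 were higher and 9 lower, and 12 of them passed in the same direction with the batch as a block. The block added calls of purine genes (median -0.43, 1 higher and 12 lower of 18), phosphate genes (0.29, 6 higher and 0 lower of 11) and TCA cycle genes (0.40, 12 higher and 1 lower of 20).

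**Figure D3:**
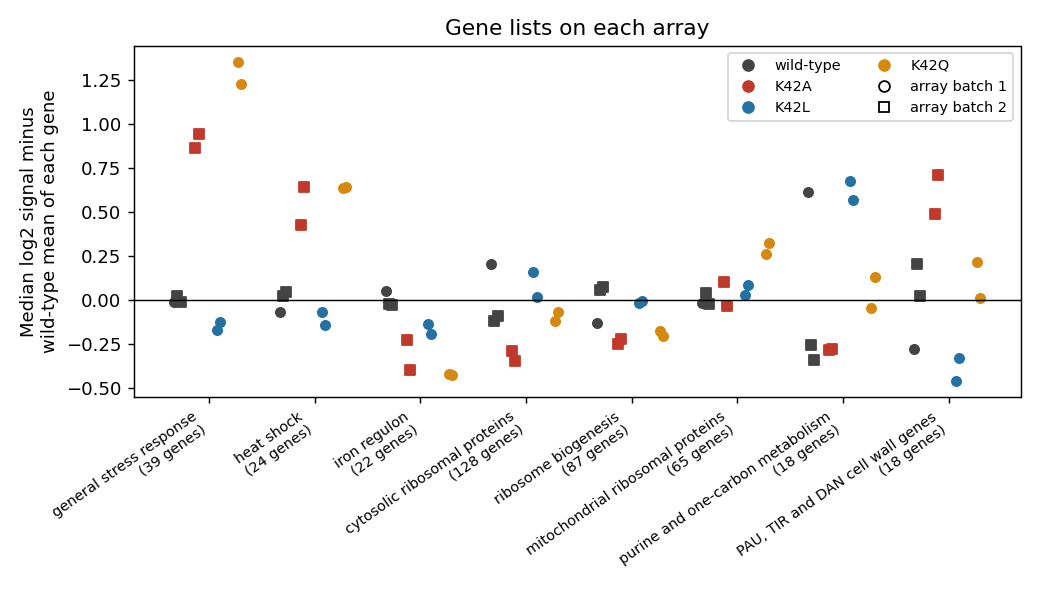
Median log2 signal of 8 gene lists on each array, relative to the wild-type mean of each gene, with colour for the group and shape for the array batch. The general stress list lies at 0.86 and 0.94 on the K42A arrays and at 1.35 and 1.23 on the K42Q arrays, and the purine list lies at 0.61 on wild-type replicate 1 and at -0.25 and -0.34 on the other wild-type arrays.

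The comparison of K42L with wild type asks the same for leucine, a larger residue than alanine. Few genes were called. GTT2 (YLL060C), for a glutathione transferase, rose by 1.53 ± 0.19 (SE, n = 2 against 3; 1.05 with the batch as a block), FET4 (YMR319C) by 1.22 ± 0.17 and FMP46 (YKR049C) by 0.90 ± 0.09. BNA1 (YJR025C), for NAD synthesis, fell by 0.94 ± 0.08, KDX1 (YKL161C) by 0.89 ± 0.09 and FIT2 by 0.87 ± 0.13. HSP12 fell by 0.64 ± 0.11, against a rise in the other mutants, and was not called with the batch as a block (-0.65, adjusted p of 0.0699). FIT2, RTA1, ADH2, DDI3, PDR10, BIO2, PLB2 and PAU3 were also called without the block and not with it. BUD20 (0.50 ± 0.07) was called, lost its call with the batch as a block (adjusted p of 0.0506), and turned to -0.036 with spike-in scaling across the batches. No histone gene was called, and ACT1 was at 0.07 ± 0.12.

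In all, 13 genes rose and 14 fell in K42L of 4087, at 722 genes with an unadjusted p under 0.05, and 2 and 0 changed by at least 2-fold. With the batch as a block the counts were 13 and 6, of which 7 and 3 were called both ways, and within the batch 24 and 25. The counts hang on single arrays: without wild-type replicate 1, which leaves the wild-type arrays of the other batch, they were 689 and 675, and without either K42L array 0 and 0. Array weights gave 1003 and 925. Leaving out K42Q replicate 1 or 2 or wild-type replicate 3 gave 1 and 2, wild-type replicate 2 gave 2 and 2, and K42A replicate 1 or 2 gave 8 and 8. Of 37 lists 3 were higher and 9 lower, 0 of them with an estimated correlation and 6 with the batch as a block in the same direction. General stress genes were lower (median -0.18, -0.14 within the batch), with 0 higher and 2 called lower of 39, 13 adjusted over the list alone, and adjusted p = 0.425 with an estimated correlation. Cell wall integrity genes (median -0.11, 1 lower of 27), PAU, TIR and DAN genes (-0.30, 1 lower of 18), heat shock genes (-0.10, 0 of 24), proteasome genes (-0.11, 0 of 36) and iron genes (-0.14, 1 higher and 1 lower of 22) were also lower with the batch as a block. Stationary phase genes (-0.29, 0 called of 5; 0.013 within the batch) and purine genes (0.61, 0 called of 18; 0.0030 within the batch) were not called there. Cytosolic ribosomal protein genes (0.09, 0 called of 128), Gcn4 targets (0.07, 0 of 55), G1 and S phase genes (-0.17, 0 of 31) and M and G1 phase genes (-0.09, 0 of 24) changed sign with the batch as a block, to -0.11, -0.031, 0.18 and 0.064. With an estimated correlation these lists had adjusted p = 0.649 or more. Called with the block alone were ribosome biogenesis (0.11), glycolysis (-0.18), oxidative phosphorylation (-0.14), phosphate genes (0.14), mitochondrial ribosomal proteins (0.08) and RNA polymerase I and III (0.07), in which 1 gene was called, of the phosphate list. Without K42L replicate 1 the number of lists called fell from 12 to 7.

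**Figure D4:**
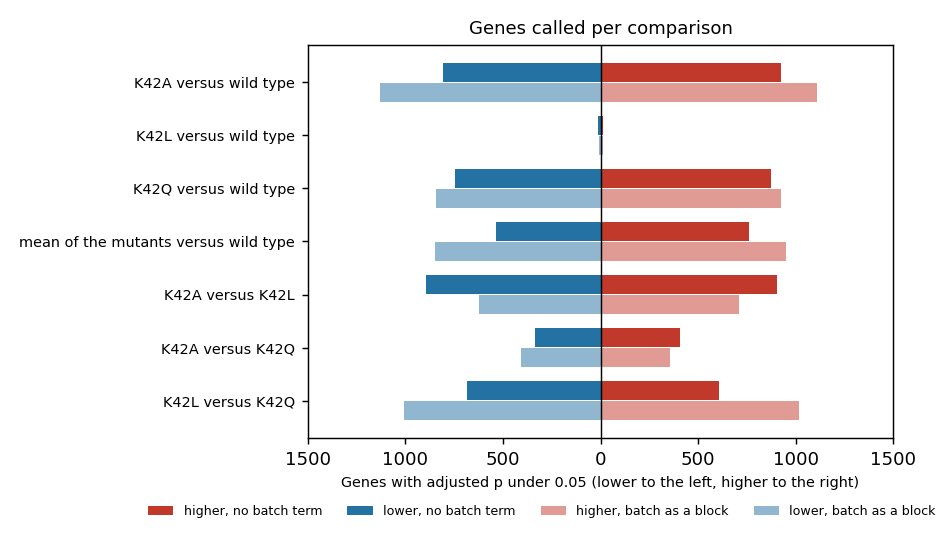
Numbers of genes called higher (to the right) and lower (to the left) in each comparison, with and without the array batch as a block. K42L against wild type has 13 and 14 calls, and the other comparisons have 333 or more in each direction without the block.

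The mean of the 3 mutants was set against wild type to ask what the substitutions share. GTT2 rose by 1.78 ± 0.15 (SE, n = 6 against 3), HPF1 (YOL155C) by 1.69 ± 0.11, NCA3 by 1.67 ± 0.14 and FMP46 by 1.51 ± 0.07. ARN2 fell by 0.97 ± 0.08, FIT2 by 0.95 ± 0.10, ENB1 by 0.92 ± 0.09 and BNA1 by 0.71 ± 0.06. Among stress genes 31 of 39 rose and 0 fell (median 0.61, 0.68 with the batch as a block; adjusted p = 0.0246 with an estimated correlation, and 0.351 with the block as well), but the list was lower in K42L (median -0.18), where TMA10, DDR2 and MSC1 overlapped wild type, so K42A and K42Q carry this mean. Of the iron list 2 rose and 12 of 22 fell (median -0.25). Of cytosolic ribosomal protein genes 7 of 128 fell (median -0.10), and with the batch as a block 104 (median -0.20). Of mitochondrial ribosomal protein genes 19 of 65 rose (median 0.14), and of ribosome biogenesis genes 24 of 87 fell (median -0.14). Each list had an adjusted p of 0.433 or more with an estimated correlation. In K42L alone the medians of these lists, in this order, were -0.14, 0.09, 0.06 and -0.01. Within the batch they were -0.16, -0.11, 0.08 and 0.11. The sign of the cytosolic ribosomal protein and ribosome biogenesis lists in K42L thus hangs on the fit. Their means do not show a change shared by the 3 substitutions. Proteasome genes (median -0.06, 3 lower of 36) turned to 0.011 under quantile and 0.03 under cyclic loess scaling and were not called with the batch as a block (adjusted p of 0.177), and had adjusted p = 0.491 with an estimated correlation. In all, 762 genes rose and 537 fell, 47 and 0 by at least 2-fold, and with the batch as a block 951 and 846. Quantile scaling gave 524 and 678, median centring 615 and 782, and spike-in scaling across the batches 36 and 9. Of the 1299 genes called, 391 had arrays of the mutants and of wild type that did not overlap. The lower count was 1026 without wild-type replicate 1, 305 without replicate 2, 298 without replicate 3 and 346 without K42L replicate 2. Of 37 lists 5 were higher and 8 lower, and 12 passed in the same direction with the block. Called with the block alone were phosphate (0.15), TCA cycle (0.19) and PAU, TIR and DAN genes (0.21), which were higher, and purine (-0.21), G2 and M phase (-0.18) and glycolysis genes (-0.19), which were lower.

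K42A and K42L were compared to ask whether the smaller and the larger hydrophobic residue differ. These groups lie in different batches, so the blocked fit links them through the wild-type arrays. DDR2 was higher in K42A by 3.19 ± 0.22 (SE, n = 2 against 2; 2.76 with the batch as a block), TMA10 by 3.02 ± 0.25 (3.77), PIR3 by 2.45 ± 0.19 (3.06), FIG2 by 2.40 ± 0.16 and SSA3 by 2.34 ± 0.23 (1.60). Of the general stress list 32 of 39 were higher and 0 lower (median 1.27, 1.15 with the block; adjusted p = 0.0316 with an estimated correlation, and 0.106 with the block as well). Of the PAU, TIR and DAN genes 15 of 18 were higher (median 1.11, 0.64 with the block; adjusted p = 0.434 with an estimated correlation). Cytosolic ribosomal protein genes had 0 higher and 101 lower of 128 (median -0.41), and with the block 17 lower (median -0.11; adjusted p = 0.434 with an estimated correlation). Ribosome biogenesis had 2 higher and 33 lower of 87 (median -0.21), and with the block 53 lower (median -0.36). Purine genes were lower in K42A, 14 of 18 (median -1.07). Both of these lists had adjusted p = 0.434 with an estimated correlation. For purine genes the block left a median of -0.13 (adjusted p of 0.344). There ADE1 went from -1.92 to 0.00089, SHM2 from -1.51 to 0.04 and CTR3 from -2.41 to 0.57. ADE17 (-2.50, adjusted p of 0.0525), ADE2 (-1.69, 0.0517) and HIS4 (-1.11, 0.122) were not called without the block and were called higher with it (0.95, 0.61 and 0.89). CTR1 (-1.82) and ADE8 (-1.55) also lost their calls with the block, while SLX9 (-1.58 ± 0.18, -0.98 with the block) was called both ways. In all, 904 genes were higher and 896 lower in K42A, and with the block 710 and 621, of which 550 and 360 were called both ways. Median centring gave 731 and 1188 and spike-in scaling across the batches 3167 and 4. Without K42L replicate 1 the counts were 502 and 326, without K42A replicate 2 554 and 370, and without K42L replicate 2 the lower count was 459. Of 37 lists 7 were higher and 9 lower, and 10 passed in the same direction with the block. With it alone, G1 and S phase (-0.34), M and G1 phase (-0.33) and histone genes (-0.23) were called lower, and glucose-repressed (0.70), oxidative phosphorylation (0.18), oxidative stress (0.13) and cell wall integrity genes (0.05) higher.

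K42A and K42Q were compared to ask whether alanine and glutamine differ. They lie in different batches, so differences without the block carry that of the batches. The blocked fit links them through the wild-type arrays. DAN and TIR genes of the cell wall were higher in K42A: DAN1 by 1.83 ± 0.22 (SE, n = 2 against 2; 1.29 with the batch as a block), TIR4 (YOR009W) by 1.72 ± 0.21 (0.99) and TIR2 (YOR010C) by 1.32 ± 0.17 (0.82). CWP1, also of the cell wall, was lower (-0.71), and the cell wall integrity list was not called (adjusted p of 0.866, and 0.596 with the block). GPH1 was lower in K42A by -1.38 ± 0.11 (-1.61 with the block) and HSP26 by -0.83, which spike-in scaling across the batches turned to 0.048. CTR3 (-2.998 ± 0.875) was not called with the block, where it was -0.01 (adjusted p of 0.989), nor was YSR3 (1.24 ± 0.25, 0.38 with the block), whereas CTR1 (-2.45 ± 0.43, -0.996 with the block) was. Genes for mitochondrial ribosomal proteins had 0 higher and 32 lower of 65 (median -0.29, -0.32 with the block), and general stress genes 1 higher and 16 lower of 39 (median -0.34, -0.36 with the block), with adjusted p = 0.57 and adjusted p = 0.281 with an estimated correlation. PAU, TIR and DAN genes had 8 higher and 0 lower of 18 (median 0.62, 0.21 with the block), heat shock genes 2 higher and 9 lower of 24 (median -0.35), and iron genes 7 higher and 1 lower of 22 (median 0.20). Cytosolic ribosomal protein genes (0 higher, 7 lower of 128, median -0.22) turned to 0.070 with the block and to 0.65 with spike-in scaling across the batches, and glycolysis (-0.31), oxidative phosphorylation (-0.22), COS genes (0.48) and the outermost genes (0.16) were called without the block and not with it. In all, 407 genes were higher and 333 lower in K42A, and with the block 357 and 405, of which 165 and 142 were called both ways. Spike-in scaling across the batches gave 2625 and 3. The counts fell without K42Q replicate 2 (64 and 59), K42Q replicate 1 (103 and 64), K42A replicate 2 (105 and 69) and K42A replicate 1 (188 and 153), and grew without wild-type replicate 1 (873 and 848). Of 37 lists 10 were called, 5 of them in the same direction with the block and 0 with an estimated correlation. With the block alone, ribosome biogenesis (median -0.25, 4 higher and 35 lower of 87), G1 and S phase (-0.33), M and G1 phase (-0.31), phosphate (-0.37) and RNA polymerase I and III genes (-0.18) were called lower in K42A. Purine (0.29), Gcn4 target (0.19), G2 and M phase (0.23), zinc (0.19) and marker genes (0.64) were called higher there.

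K42L and K42Q were compared inside their common batch, so the fold changes carry no batch difference. Stress genes were lower in K42L: TMA10 by -3.48 ± 0.25 (SE, n = 2 against 2), DDR2 by -3.18 ± 0.22, HSP12 by -3.12 ± 0.12, EGO4 by -3.06 ± 0.13, GPH1 by -3.03 ± 0.11 and HSP26 by -2.93 ± 0.10. DAN1 was higher in K42L by 1.52 ± 0.22, RPS22B by 1.19 ± 0.10, ARN2 by 1.17 ± 0.12 and DBP2 by 1.13 ± 0.07, and HIS3 by 1.83 ± 0.59. Of the general stress list 0 were higher and 33 of 39 lower (median -1.53; adjusted p = 0.0113 with an estimated correlation, and 0.203 with the block as well). Mitochondrial ribosomal protein genes had 0 higher and 25 lower of 65 (median -0.26), TCA cycle genes 2 higher and 12 lower of 20 (median -0.37), and phosphate genes 0 higher and 3 lower of 11 (median -0.32). Oxidative phosphorylation had 1 higher and 9 lower of 31 (median -0.18), sulphate and methionine genes 1 higher and 4 lower of 23 (median -0.23), and glucose-repressed genes 1 higher and 5 lower of 8 (median -0.55, adjusted p of 0.0546 with the batch as a block). Ribosome biogenesis had 22 higher and 0 lower of 87 (median 0.14), cytosolic ribosomal proteins 17 higher and 0 lower of 128 (median 0.19), Gcn4 targets 22 higher and 4 lower of 55 (median 0.31) and purine genes 5 higher and 0 lower of 18 (median 0.44). With an estimated correlation these lists had adjusted p = 0.338 or more. Lipid synthesis (median 0.10, 5 higher and 2 lower of 31) turned to -0.02 under quantile and -0.06 under cyclic loess scaling, and had adjusted p = 0.338 with an estimated correlation. In all, 606 genes were higher and 682 lower in K42L, with the batch as a block 1018 and 1008, and in the fit of that batch alone 1019 and 1047. Spike-in scaling within the batch gave 507 and 1533, and across the batches 2 and 105. The counts were 237 and 321 without K42L replicate 1, 279 and 396 without replicate 2, 281 and 353 without K42Q replicate 1 and 331 and 433 without replicate 2, and without wild-type replicate 1 the higher count was 1015. Of 37 lists 10 were higher and 14 lower, and 22 passed in the same direction with the batch as a block.

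K42A and K42Q shared many calls against wild type. Both had TMA10, DDR2, MSC1, EGO4 and GTT2 higher and RPS22B, FIT2, FET3 and YLR126C lower. In all, 568 genes were higher in both and 427 lower in both, against 198 and 147 for independent lists of these sizes, and 19 were called in opposite directions. Across 4087 genes, which are not independent replicates, the fold changes had r = 0.739 and a covariance of 0.131. The comparisons share the wild-type arrays. In 100 simulations of unchanged groups against shared controls r averaged 0.403 and the covariance 0.0053, and at most 0 genes were called in both. The simulations held no batch difference. Such a difference can raise the covariance of mutants in the same batch and lower that of mutants in different batches. Fitted within their batches these comparisons share no control, and they gave 601 and 497 shared genes, against 256 and 225 for independent lists, 66 opposite ones, r = 0.683 and a covariance of 0.125. K42A and K42L shared 10 higher and 3 lower genes (2.94 and 2.76 for independent lists), with 11 opposite, a covariance of 0.00099 against a simulated 0.0053, and r = 0.0111. They lie in different batches, so the simulated value is not that of no change here either. Fitted within their batches, with no shared control, they had a covariance of 0.0024 and r = 0.0353. K42L and K42Q shared 8 and 4 (2.78 and 2.55 for independent lists), with 6 opposite, a covariance of 0.0267 against a simulated 0.0053, and r = 0.293 against a simulated 0.400. They lie in the same batch, so the simulated values are not those of no change for this pair. The within-batch fits of K42L and K42Q share wild-type replicate 1 and gave r = 0.302 and a covariance of 0.0212. No simulation was run for a single shared array, so these values cannot be read as shared change. Without wild-type replicate 1 the shared calls were 530 for K42A and K42L and 795 for K42L and K42Q. The wild-type arrays left are of the other batch than K42L and K42Q, whose fold changes then carry the batch difference. These 2 values therefore cannot be read as shared change. Without K42L replicate 1 the shared calls of both pairs were 0. The calls that K42A and K42Q shared in the same direction, 995 in all, fell to 592 without K42Q replicate 1 and to 649 without K42A replicate 2.

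Dim genes tended to rise and bright genes to fall in K42A and K42Q, so their levels moved closer together. With genes split into 5 groups of equal size by mean signal, in the dimmest group (median signal 111) 304 rose and 59 fell in K42A, with a median of 0.19, and in the brightest (median signal 1067), 39 rose and 345 fell, with a median of -0.25. In K42Q the dimmest group had 298 higher and 53 lower (median 0.20) and the brightest 52 higher and 242 lower (median -0.11). In K42L the medians were 0.05 and 0.03. The brightest minus the dimmest group was -0.43 in K42A and -0.31 in K42Q, and under quantile scaling 0.0014 and -0.028, and under cyclic loess 0.013 and -0.0034, since these methods align the signal distributions.

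**Figure D5:**
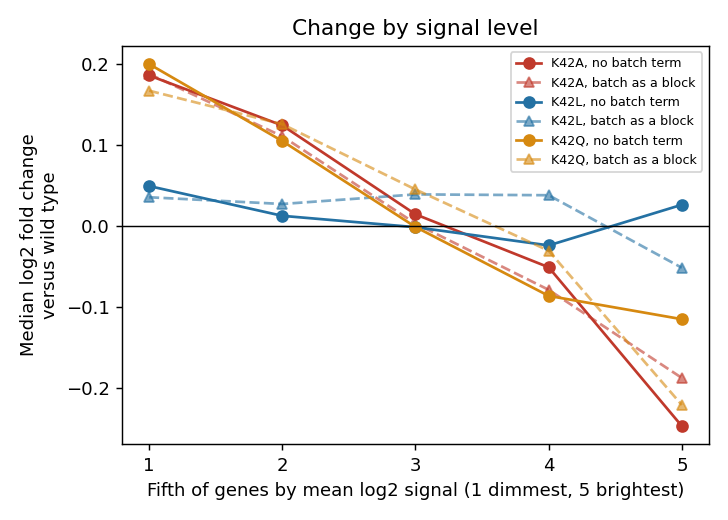
Median log2 fold change against wild type in each of 5 groups of genes by mean log2 signal, with lines for each mutant with and without the array batch as a block. K42A runs from 0.19 in the dimmest to -0.25 in the brightest group without the block, and the trend of K42A and K42Q is absent under quantile and cyclic loess scaling.

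Lists with no called shift in any comparison without a batch term were those of the histones, the marker genes, H3 methylation and elongation factors, hexose transporters, the zinc regulon and silencing factors, and the flocculation and filament genes. With the batch as a block, histones were called lower in K42A than in K42L (adjusted p of 0.0481), zinc genes higher in K42A than in K42Q (0.048), and marker genes higher in K42A (0.048) and K42L (0.0248) than in K42Q. These 4 calls had adjusted p = 0.311 or more with an estimated correlation. Within the batch, histones were called lower in K42A (adjusted p = 0.651 with an estimated correlation) and marker genes higher in K42L than in K42Q (0.0282). The largest change among the 4 marker genes there is that of HIS3, which rests on K42Q replicate 2. The list of H3 methylation and elongation factors had 3 higher and 4 lower of 26 in K42A (median 0.03) and 2 higher and 4 lower in K42Q (median 0.04), and median centring turned these medians to -0.05 and -0.0060. Silencing factors had 2 higher and 1 lower of 16 in K42A (median 0.02, and -0.06 under median centring). The galactose, alpha-specific, meiosis and telomeric helicase lists had fewer than 4 measured genes and were not tested.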

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

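All tests of explanations below were chosen after the results were seen. Control probe sets for 25S ribosomal RNA, which entered no comparison, were flagged because they stood above wild type in both K42A cultures: the lowest K42A signal was 2.27 and 2.81 times the highest wild-type signal in the 2 probe sets. They were picked after seeing the values, out of 19 ribosomal RNA control probe sets, as those above all other arrays on both K42A arrays with a mean signal over 20. In the probe set nearer the 3' end K42A had 252 and 558, and all other arrays had 48.3 to 105. K42A and K42Q lie in different batches with wild type in both, so without the block a batch difference alone can give opposite signs. Flagged as a difference between the mutants, 19 genes were called in opposite directions in K42A and K42Q with their difference called too. They include TIR4 (1.04 and -0.67), CWP1 (-0.34 and 0.37), CTR2 (0.43 and -0.31) and COS7 (0.25 and -0.32), and with the batch as a block 64 genes were opposite, 11 of them in both. CWP1 and CTR2 are among those 11, while TIR4 and COS7 were not called in K42Q with the block (adjusted p of 0.0977 and 0.0864). The list of mitochondrial ribosomal proteins was flagged for the same reason, with a median of -0.29 in K42A less K42Q (adjusted p of 2.62e-11, and adjusted p = 0.57 with an estimated correlation).

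The higher general stress genes in K42A and K42Q are weighed first. Array batch was tested by the fits within the batch, where the lower of both medians was 0.99. This argues against batch as the cause of the higher medians. With an estimated correlation the list was not called there in either mutant (adjusted p = 0.476 in K42A). So few arrays remain there that hardly any list could pass, so that result decides nothing. Scaling was tested by quantile, median and cyclic loess scaling and by spike-ins within the batch, where the lowest median was 0.81, under median centring, which argues against scaling. Slower growth would lower ribosome biogenesis genes in both mutants. Within the batch they were at -0.286 ± 0.0235 in K42A and at 0.00905 ± 0.0263 (bootstrap SE) in K42Q. This SE comes from resampling the genes of the list, so it does not measure the spread of cultures. K42Q rests there on wild-type replicate 1 alone. Relative to the wild-type mean, that array lay at -0.13 on this list, and wild-type replicates 2 and 3 at 0.058 and 0.074. Growth stays undecided. The bound of that test was changed after its value had been seen, from above 0 to above 0 by more than its SE, and under the first bound the value would have counted against growth.

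The split of the wild-type arrays in purine genes is weighed second. A general shift by signal level was tested against 10000 random lists matched on expression, of which the purine list lay at percentile 100, which argues against it. A change in the strain or culture of wild-type replicate 1 alone was tested by the mutants of its batch, and 4 of their 4 arrays lay above every array of the other batch, which argues against it. Medium or culture conditions shared within a batch would set the batches apart, and the gap between them was 0.395 log2, but the batch also differs in array handling, so this stays undecided. No other biological explanation was tested.

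The opposite trends of bright and dim genes in K42A and K42Q are weighed last. Compression of the signal range was tested on spike-ins, whose bright less dim difference was at least 0.0225 in both mutants. This argues against compression in the steps that the spike-ins went through, though only 2 bright and 3 dim probe sets carry the test. Spike-ins cannot show compression in steps before they were added, so that stays undecided. Batch was tested within the batch, where the lower trend was -0.388, which argues against batch. A few gene classes were tested by leaving out all lists, which kept 3098 genes and a trend down to -0.367. This argues against the listed genes alone as the source. Genes of such classes that are on no list stayed in, so wider classes stay undecided. No biological explanation was tested.

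The calls of the mean of the mutants were set against all 84 splits of the arrays into 6 and 3. In a fit with 2 groups the real split called 3 genes, 4 splits called as many or more, the real one included, and the highest other split called 661, with K42Q replicate 1 and both K42A arrays as the set of 3. These splits follow the structure of the samples, since K42L lies with wild type, so the 2-group count is no measure of the fit with a mean per group, which called 1299.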

How the results depend on the processing

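Most named results held their side of the threshold. Over the alternatives, values of named genes were the same 10269 times, weaker 828, stronger 243 and reversed 69. Those of gene lists were the same 2307 times, weaker 348 and reversed 23. A gene called neither in the main fit nor in the alternative counted as the same even where its sign turned. The number of same values is therefore not a count of directions held. Many named genes were also picked as the largest calls of these data, which favours the same. Median centring, the fit with no intensity trend, robust hyperparameters, all probe sets and the mean of a gene's probe sets moved no count by over 1.5 times and turned the sign of no named gene or list that was called with or without them. Among lists not called, median centring turned, for example, the zinc list of K42A to -0.0026 and its oxidative stress list to -0.033. Signal over background limits what could be tested, since genes with a mean signal under 87.0 were left out and the filter changes the share of higher genes. Robust hyperparameters and the 2-fold threshold were not run for the gene lists. The batch block, the fits within the batch and both spike-in scalings were chosen after the data were seen, and the spike-in scaling within the batch was added because the mean spike-in signal of the batches differed, at 418 to 474 against 211 to 265. That difference puts batch into the scaling across the batches, so its values for K42A against the other groups carry it by construction. Filters, thresholds and left-out arrays change the number of genes or arrays tested; for the other changes below the cause was not tested. The replicate numbers do not pair the arrays: 0 of the 8 arrays with the number 1 or 2 correlated best with an array of their own number, in deviations from the group means. With the replicate number as a block, the counts of genes were 0 higher and 1 lower for K42L and 413 higher and 208 lower for the mean of the mutants. Genes called alike numbered 1 in K42A and K42L and 1 in K42L and K42Q.

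Without the filter on low signals, the counts of genes were 1676 higher for K42A, 25 higher for K42L, 1566 higher for K42Q, 1415 higher for the mean of the mutants, 1587 higher for K42A less K42L and 1253 lower for K42L less K42Q. Genes called alike numbered 26 in K42A and K42L, 1575 in K42A and K42Q and 25 in K42L and K42Q. The median of the brightest less that of the dimmest genes was -0.87 in K42A and -0.66 in K42Q. With genes above the median signal alone, the counts of genes were 422 higher for K42A, 407 higher for K42Q, 324 higher for the mean of the mutants, 457 higher for K42A less K42L and 353 lower for K42L less K42Q. Genes called alike numbered 606 in K42A and K42Q and 7 in K42L and K42Q. Lists called numbered 14 in K42L less K42Q. The median of the brightest less that of the dimmest genes was -0.35 in K42A and -0.14 in K42Q. With a change of at least 2-fold also required, the counts of genes were 127 higher and 2 lower for K42A, 2 higher and 0 lower for K42L, 110 higher and 17 lower for K42Q, 47 higher and 0 lower for the mean of the mutants, 142 higher and 24 lower for K42A less K42L, 14 higher and 11 lower for K42A less K42Q and 10 higher and 113 lower for K42L less K42Q. Genes called alike numbered 2 in K42A and K42L, 74 in K42A and K42Q and 1 in K42L and K42Q. With 16 added before the logarithm, the counts of genes were 8 lower for K42L. Under quantile scaling, the median of the brightest less that of the dimmest genes was 0.0014 in K42A and -0.028 in K42Q. For K42A the sign turned with lipid synthesis list 0.0043 and HTA2 0.011. For the mean of the mutants the sign turned with proteasome list 0.011. For K42A less K42L the sign turned with lipid synthesis list 0.038. For K42L less K42Q the sign turned with lipid synthesis list -0.022. Under cyclic loess scaling, the median of the brightest less that of the dimmest genes was 0.013 in K42A and -0.0034 in K42Q. For K42A the sign turned with lipid synthesis list 0.025 and HTA2 0.021. For the mean of the mutants the sign turned with proteasome list 0.031. For K42A less K42L the sign turned with lipid synthesis list 0.032 and HHT2 0.0022. For K42L less K42Q the sign turned with lipid synthesis list -0.057 and ACT1 -0.11. With the arrays of the compared groups alone, the counts of genes were 488 lower for K42A, 0 higher and 0 lower for K42L, 656 higher and 636 lower for K42A less K42Q and 1014 higher and 1048 lower for K42L less K42Q. With array weights, the counts of genes were 1003 higher and 925 lower for K42L, 1243 lower for K42Q, 1269 higher and 1214 lower for the mean of the mutants, 693 higher and 650 lower for K42A less K42Q and 1048 higher and 1057 lower for K42L less K42Q. With an estimated correlation in camera, lists called numbered 1 in K42A, 0 in K42L, 1 in K42Q, 1 in the mean of the mutants, 1 in K42A less K42L, 0 in K42A less K42Q and 1 in K42L less K42Q. With the batch as a block, the counts of genes were 6 lower for K42L, 846 lower for the mean of the mutants and 1018 higher for K42L less K42Q. For K42L the sign turned with cytosolic ribosomal protein list -0.11, Gcn4 target list -0.031, G1 and S phase list 0.18 and M and G1 phase list 0.064. For K42Q the sign turned with HIS4 -0.37 and RPL41A 0.96. For K42A less K42L the sign turned with ADE1 0.00089, ADE17 0.95, ADE2 0.61, CTR3 0.57, HHO1 -0.50, HIS4 0.89 and SHM2 0.043. For K42A less K42Q the sign turned with cytosolic ribosomal protein list 0.070 and RPL41A -1.58. Within the batch, the counts of genes were 24 higher and 25 lower for K42L and 1019 higher and 1047 lower for K42L less K42Q. For K42L the sign turned with cytosolic ribosomal protein list -0.11, Gcn4 target list -0.031, G1 and S phase list 0.18 and M and G1 phase list 0.064. For K42Q the sign turned with HIS4 -0.37 and RPL41A 0.96. Within the batch, with the arrays scaled to the spike-ins, the counts of genes were 115 lower for K42A, 60 higher and 23 lower for K42L, 1636 higher and 357 lower for K42Q and 1533 lower for K42L less K42Q. For K42A the sign turned with HTA2 0.0034. For K42L the sign turned with cytosolic ribosomal protein list -0.067, Gcn4 target list 0.013, G1 and S phase list 0.23, M and G1 phase list 0.11 and RPL41A 1.44. For K42Q the sign turned with RPL41A 1.14. Across the batches, with the arrays scaled to the spike-ins, the counts of genes were 567 higher and 0 lower for K42A, 2 higher for K42L, 49 higher and 79 lower for K42Q, 36 higher and 9 lower for the mean of the mutants, 3167 higher and 4 lower for K42A less K42L, 2625 higher and 3 lower for K42A less K42Q and 2 higher and 105 lower for K42L less K42Q. Genes called alike numbered 0 in K42A and K42L, 46 in K42A and K42Q and 3 in K42L and K42Q. For K42A the sign turned with HHF1 0.27, HTA1 0.10, HTA2 0.24, HTB1 0.22, RPB5 0.11, RPB8 0.14 and RPO26 0.12. For K42L the sign turned with cytosolic ribosomal protein list -0.44 and BUD20 -0.036. For K42A less K42L the sign turned with ACM1 0.28, ACT1 0.67, AGA2 0.40, BUD20 0.13, CLB1 0.17, CLB2 0.26, HHF1 0.91, HHT2 0.69, HTA1 0.63, HTA2 0.68, HTB1 0.72, MFA1 0.079, NOP7 0.29, OLE1 0.37, RPA190 0.38, RPB10 0.62, RPB5 0.57, RPC53 0.27, RPL22B 0.27, RPO26 0.59, RPS19A 0.33, STE6 0.25 and UTP13 0.32. For K42A less K42Q the sign turned with cytosolic ribosomal protein list 0.65, ACT1 0.60, COX5B 0.28, CYC1 0.16, GLK1 0.49, HHF1 0.77, HHT2 0.57, HSP26 0.048, HTA1 0.72, HTA2 0.70, HTB1 0.70, HTB2 0.80, MRP49 0.21, MRPL44 0.27, QCR9 0.14, RPS14B 0.36, RPS28A 0.44, RSM27 0.24, SSA4 0.18 and TDH1 0.25.

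The turns of gene lists above are those of the test against all other genes, and there the median of the Gcn4 targets of K42L stayed at 0.013. Medians of called lists also changed sign where that test did not turn. Without the filter on low signals these were pheromone 0.16 in K42Q. Under cyclic loess scaling these were cytosolic ribosomal proteins 0.012 in K42Q, and cytosolic ribosomal proteins 0.0053 and lipid synthesis 0.0059 in the mean of the mutants. Under the batch block these were stationary phase 0.013 in K42L, and ribosome biogenesis 0.0091 in K42Q, and glycolysis 0.026 in K42A less K42Q. Within the batch these were stationary phase 0.013 in K42L, and ribosome biogenesis 0.0091 in K42Q. With spike-in scaling within the batch these were purine 0.053 and lipid synthesis 0.045 in K42A, and stationary phase 0.057 in K42L, and ribosome biogenesis 0.18, RNA polymerase I and III 0.076 and lipid synthesis 0.03 in K42Q, and RNA polymerase II -0.0057 and lipid synthesis -0.031 in K42L less K42Q. With spike-in scaling across the batches these were RNA polymerase II 0.26, cytosolic ribosomal proteins 0.16, ribosome biogenesis 0.27, RNA polymerase I and III 0.22, Gcn4 targets 0.19, purine 0.18, lipid synthesis 0.31 and iron 0.16 in K42A, and Gcn4 targets -0.46 in K42L, and mitochondrial ribosomal proteins -0.10, DNA damage -0.18, oxidative stress -0.12 and outermost genes -0.29 in K42Q, and mitochondrial ribosomal proteins -0.016 and outermost genes -0.057 in the mean of the mutants, and RNA polymerase II 0.79, cytosolic ribosomal proteins 0.60, ribosome biogenesis 0.80, RNA polymerase I and III 0.73, Gcn4 targets 0.64, lipid synthesis 0.83, a-specific genes 0.42 and G2 and M phase 0.79 in K42A less K42L, and mitochondrial ribosomal proteins 0.58, general stress 0.54, heat shock 0.53, glycolysis 0.57 and oxidative phosphorylation 0.66 in K42A less K42Q, and RNA polymerase II -0.0057 and lipid synthesis -0.031 in K42L less K42Q.

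Leaving out 1 array at a time gave these lowest and highest values, with a lone array of a group assumed to vary like the other groups. For K42A, 587 to 1112 genes were higher, 334 to 1126 lower and 15 to 18 lists called. For K42L, 0 to 689 genes were higher, 0 to 675 lower and 7 to 15 lists called. For K42Q, 477 to 1185 genes were higher, 377 to 1137 lower and 12 to 17 lists called. For the mean of the mutants, 510 to 1085 genes were higher, 298 to 1026 lower and 12 to 14 lists called. For K42A less K42L, 502 to 1208 genes were higher, 326 to 1254 lower and 15 to 18 lists called. For K42A less K42Q, 64 to 873 genes were higher, 59 to 848 lower and 7 to 12 lists called. For K42L less K42Q, 237 to 1015 genes were higher, 321 to 1008 lower and 20 to 24 lists called. Genes called alike ran from 0 to 530 in K42A and K42L, 592 to 1473 in K42A and K42Q, 0 to 795 in K42L and K42Q. The highest of these came without wild-type replicate 1, where fold changes of K42L and K42Q against wild type carry the batch difference. No value of a named gene or list called with all arrays or without 1 changed sign. Some uncalled values did, among them RPL41A in K42L, from -0.38 to 0.087 without wild-type replicate 2 and to 0.045 without replicate 3, and HTB2 in K42A, from -0.013 to 0.024 without wild-type replicate 2.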

Other observations

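PHO84, for phosphate uptake, and MET17, for methionine synthesis, differed between the wild-type arrays. PHO84 had a signal of 41.6 in wild-type replicate 1 and of 65.6 and 70.8 in K42L, and of 551.5 to 852 on the other arrays. It was called in no comparison without the batch as a block. With the block it was at 4.01 in K42Q and 0.71 in K42L, which rest on wild-type replicate 1, and at -0.43 in K42A (adjusted p of 1.14e-09, 0.0138 and 0.00154). MET17 lay under the filter, with 260.4 in wild-type replicate 1, 132 and 138 in the other wild-type cultures and 31.6 to 78.0 in the mutants, and LYS2 lay between 3.6 and 17.4. RPL41A was called higher in K42L and in K42Q with spike-in scaling within the batch, by 1.44 and 1.14. These genes were chosen after their values were seen, and no explanation was tested.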
